A study of Vaccinium macrocarpon
Vaccinium oxycoccos and Vaccinium macrocarpon and Vaccinium oxycoccos with 94 samples.

How the data were processed

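Leaf transcripts were measured in 94 libraries from the American cranberry Vaccinium macrocarpon cv. Stevens, 4 F1 hybrid genotypes and the wild relative Vaccinium oxycoccos. The labels give the crosses of the hybrids as Ben Lear by an NJ96 selection (the Ben Lear hybrid), Pilgrim by an NJ96 selection (the Pilgrim hybrid), NJ96-20 × Stevens and Stevens × NJ96-95, where Ben Lear, Pilgrim and Stevens are cranberry cultivars. Per the labels' protocols, hybrids sharing a genotype name were rooted from cuttings of 1 seedling, plants were held for 3 days at 21 °C, and leaves were taken after 0, 15 or 30 min in an incubator preset to 45 °C or after 0, 60 or 95 min in one set to 2 °C. The stated temperatures at harvest were 39.7 °C and 47 °C in the heat series and 10.5 °C and 3 °C in the cold series. Also per the labels' protocols, full-length cDNA from 200 ng of total RNA was amplified with 16 PCR cycles and barcoded, cDNA from 9 samples was pooled per run, and each run was sequenced for 72 h on an Oxford Nanopore PromethION. Which libraries shared a run is not given in the sources used here, so sequencing run and genotype may coincide.

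The deposited quantification table holds estimated counts per gene model and library, in the column layout that Salmon writes. The submitters' processing notes name minimap2 2.28-r1209 and Salmon 1.6.0, without their settings. Per the file headers and feature names, every library was quantified against 58887 gene models at once, 30005 named for V. macrocarpon and 28882 for V. oxycoccos, called features here. The deposited TPM values equalled each count's share of its library, scaled as CPM (largest difference 0.00106), because the effective length was listed as 100 for each feature, so no length correction entered them. Model lengths were also listed in the deposited table. A read from a sequence that both species share can be assigned to either copy, and how the authors resolved such reads is not given in the sources used here. No genome or annotation was used. The feature names hold a species, a chromosome and a number and pair no identifier with a gene name. The 24 gene lists fixed before the data were examined therefore matched 0 features, and the planned tests of these lists were not run. Pairs of copies between the species were not matched either.

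Samples were grouped by genotype, series and time from their titles into 30 groups of 3 libraries and 1 group of 4 V. oxycoccos plants, each of a different genotype. In 2 samples the library name carried another time code than the title, and the title was used. Nothing in the labels says whether the 3 replicates of a group came from separate plants, so p-values measure the spread between these samples, which may be technical. Library totals ran from 461274 to 10787153 reads. No replicate pair agreed within sampling noise: chi-square per degree of freedom over features was 2.31 in the closest pair.

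Estimated counts were rounded to whole numbers (99.9% were whole within 1e-06) and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, robust quasi-likelihood F test, 2-sided). A feature was called at a Benjamini-Hochberg adjusted p under 0.05. The heat series (45 libraries, 26592 features tested) and the cold series (45 libraries, 29056 features) were each fitted with 1 coefficient per group, and the 0 min libraries of both series with the V. oxycoccos plants (34 libraries, 28437 features) in a further model. Contrasts were each time against 0 min within a genotype, the mean of the 4 hybrids, and the difference between that mean and Stevens in the response (interaction). The times of 1 series share their 0 min libraries. Standard errors were taken as the absolute log2 fold change divided by the square root of F. Log2 fold changes are edgeR's estimates. Where 1 side of a comparison held 0 reads, the ratio was set against 3 reads over its pooled libraries and is a lower bound, and 95% Clopper-Pearson intervals of pooled ratios cover counting error only, since reads copied by PCR are not independent molecules.

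By the rule fixed before the data were examined for identifiers without names, at most 2 features that rose and 2 that fell are named per main comparison. They are those of largest absolute log2 fold change among called features with a mean of at least 5 CPM in the higher group and with every library of 1 side above every library of the other. The last condition was applied within each hybrid for the hybrid mean and dropped for interactions. Where a comparison called 5 features or fewer, those outside the rule are named too and marked as chosen after their values were seen.

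Tested on simulated counts with 200 changed features, the fit recovered 35% of 4-fold changes and 6% of 2-fold changes for Stevens at 30 min of heat, and 85% and 47% for the hybrid mean. For the cold series at 95 min these shares were 36% and 2% in Stevens, 20% and 1% in NJ96-20 × Stevens, and 83% and 47% for the hybrid mean. Single genotypes thus had low power for 2-fold changes, and counts of calls in a genotype and in the hybrid mean rest on 6 and 24 libraries. The simulated counts took their spread from its fitted trend with abundance, without a spread of each feature's own. The changed features had a mean of at least 1 CPM, so these shares need not hold for real or rarer features. They were drawn from both species' models. Oxycoccos features hold few reads in Stevens, so its shares may understate the power for macrocarpon features.

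Shares of reads on oxycoccos features were compared by exact permutation tests of library values or, for larger groups, by 100000 resamples. The number of features detected was compared after rarefying every library to 461274 reads. A heat set was also scored in each genotype. It was chosen from the other 4 genotypes alone, as the macrocarpon features called in at least 3 of them at 30 min, and its score was the mean log2 CPM (prior count 2) minus the 0 min mean. Scores were compared by exact permutation of libraries. Alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, the replicate number as a block, a fit to the libraries of 1 genotype, 0 min libraries of 1 series, each library left out in turn, libraries thinned to equal depth and a fit of macrocarpon features alone. The last 2, the heat set and the map of neighbouring features were chosen after the data had been seen.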

Results

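Leaf transcript abundance was measured by nanopore sequencing of full-length cDNA in 94 libraries, to compare the responses of cultivated cranberry and of its F1 hybrids with a wild relative to short heat and cold. Stevens, a cultivar of V. macrocarpon, gave 18 libraries and the 4 hybrids 72, with 3 libraries per genotype at 0, 15 and 30 min of heat and at 0, 60 and 95 min of cold. V. oxycoccos, the wild relative, was represented by 4 unstressed plants of 4 genotypes, whose names match none of the parents listed for the hybrids. Library totals ran from 2915014 to 6315963 reads in Stevens, from 1373291 to 3340578 in the heat series of the hybrids, and from 4621168 to 10787153 in V. oxycoccos. In the cold series, the Ben Lear and NJ96-20 × Stevens hybrids were shallow, with 461274 to 1074094 reads, and the other hybrids had 2493628 to 4526870. The most abundant single feature took between 1.3% and 15.7% of a library. Stevens was the only macrocarpon genotype, so any difference from the hybrids is between 1 genotype and 4.

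Every library was quantified against gene models of both species, and the share of reads on oxycoccos features rose from Stevens through the hybrids to V. oxycoccos. The sources used here do not give the ploidy of the hybrids or of V. oxycoccos, so no share is set as the one a pedigree predicts. The share was 8.27% in Stevens at 0 min (n = 6), 45.0% in the hybrids at 0 min (n = 24) and 78.4% ± 7.8 (SD, n = 4) in V. oxycoccos. The hybrids lay 36.7 percentage points above Stevens (2-sided permutation test of libraries, p = 1e-05, the smallest that 100000 resamples can give), and V. oxycoccos 33.4 points above the hybrids (exact permutation p = 4.88e-05) and 70.1 points above Stevens (exact permutation p = 0.00476). These tests take libraries as units. With genotypes as the unit, 1 Stevens genotype against 4 cannot give a p below 0.2. Since Stevens holds no oxycoccos parent, its 8.27% gives the background of reads assigned to the other species. Over all libraries, the hybrid means were 45.4% ± 1.1 for the Ben Lear hybrid, 44.7% ± 0.9 for NJ96-20 × Stevens, 44.6% ± 2.7 for the Pilgrim hybrid and 43.7% ± 1.0 for Stevens × NJ96-95 (SD, n = 18 each). The single most abundant feature, a macrocarpon one, lowered these shares. Without it the 72 hybrid libraries averaged 48.1% ± 1.2, against 44.6% ± 1.7 with it (SD). Over 24 comparisons of stressed libraries with 0 min, the lowest Benjamini-Hochberg adjusted p was 0.518 (exact and stratified permutation tests). Within 1 genotype, 3 libraries against 3 cannot give a p below 0.1, so a stable share is not shown there: Stevens went from 8.15% at 0 min of heat to 9.35% at 15 min and 9.19% at 30 min, and its 6 heated libraries (8.79% to 9.97%) all lay above its 3 at 0 min (8.01% to 8.34%; exact permutation p = 0.1 at each time). In the same Stevens groups, the 5 oxycoccos features of the chromosome 7 group described below went from 18.4 to 8590 and 11200 CPM. That gain is close in size to the rise in share, so the rise need not be spread over many oxycoccos features. In V. oxycoccos, plant 4 stood at 66.8% and the other 3 averaged 82.3%.

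**Figure D1:**
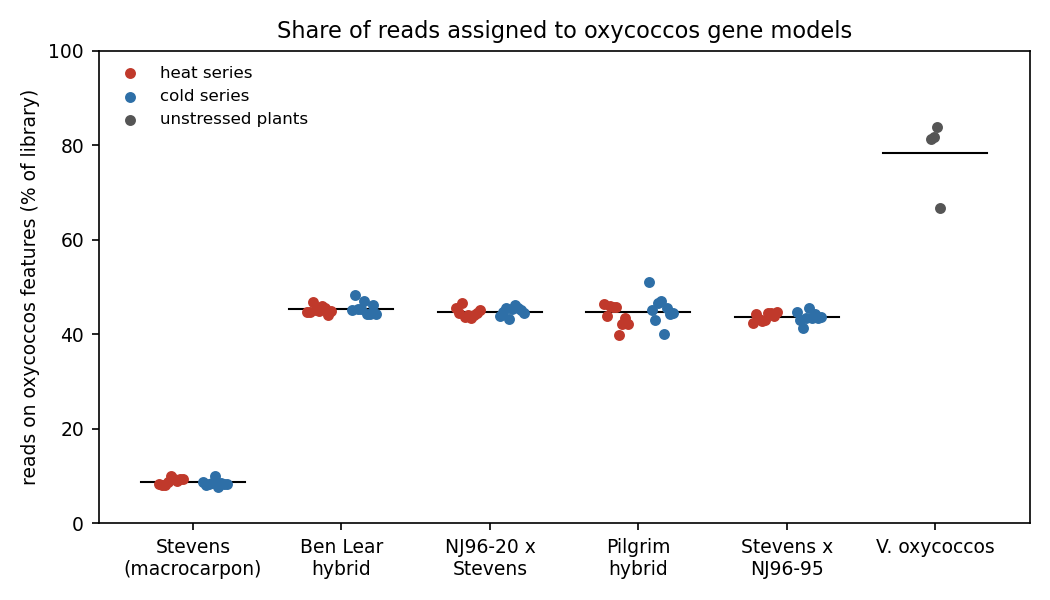
Percent of each library's reads assigned to oxycoccos features (vertical axis) by genotype (horizontal axis), with heat-series libraries in red, cold-series libraries in blue and unstressed V. oxycoccos plants in grey; black lines are means. Stevens libraries lie between 7.67% and 9.98%, hybrid libraries between 39.8% and 51.1%, and V. oxycoccos between 66.8% and 83.8%.

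At 0 min, oxycoccos features were higher and macrocarpon features lower in the hybrids than in Stevens. Of 28437 features tested by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), 12009 were higher and 6096 lower. The higher ones included 82.3% of the oxycoccos features tested, and the lower ones 41.1% of the macrocarpon features. The median log2 fold change was 4.07 over oxycoccos features and −0.67 over macrocarpon features. Stevens holds no oxycoccos parent, so these calls do not tell the genome carried from regulation. When macrocarpon features were scaled by themselves, a fit chosen after the data had been seen, the 6313 macrocarpon calls (417 higher, 5896 lower) became 1822 (922 higher, 900 lower) and their median −0.03. Among the features named by the fixed rule, Vaccinium_oxycoccos.helixer.a04.chr01.g021380 stood at 3490 CPM over the 24 hybrid libraries and 0.418 CPM over the 6 Stevens libraries, a ratio of 8360 (95% interval 4670 to 16800), and Vaccinium_oxycoccos.helixer.a04.chr03.g062990 at 469 CPM against a single Stevens read, a ratio of 12400 (2220 to 488000). In the other direction, Vaccinium_macrocarpon.helixer.a04.chr01.g022400 had 37.2 CPM in Stevens and 0 reads in the hybrids, at least 600-fold lower, although its adjusted p was 0.000187 with edgeR and 0.0667 with DESeq2. Vaccinium_macrocarpon.helixer.a04.chr06.g150230 had 17.4 CPM in Stevens and 3 reads in the hybrids, a ratio of 281 (95.7 to 1370).

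V. oxycoccos differed from Stevens in 23776 of the 28437 features, 13663 higher and 10113 lower, with 90.6% of the tested oxycoccos features higher and 68.1% of the tested macrocarpon features lower. Here too the calls do not tell the genome carried from regulation. Neighbouring oxycoccos features on chromosome 4 led the rise: Vaccinium_oxycoccos.helixer.a04.chr04.g079600 stood at 3270 CPM with 0 reads in Stevens, at least 28700-fold higher, and Vaccinium_oxycoccos.helixer.a04.chr04.g079590 at 3010 CPM, a ratio of 11300 (95% interval 5490 to 28200). On the log2 scale the rises of this pair were 16.59 ± 2.24 and 14.68 ± 1.89 SE, and 15.73 and 13.64 without plant 3. The interval covers counting error and not this spread between plants. Vaccinium_macrocarpon.helixer.a04.chr11.g274180 and Vaccinium_macrocarpon.helixer.a04.chr07.g182040 stood at 1400 and 240 CPM in Stevens with 0 reads in V. oxycoccos, at least 14900-fold and 2540-fold lower. Against the mean of the hybrids, 9867 features were higher and 8432 lower in V. oxycoccos (9984 and 10243 without plant 4). RLE scaling shifted every log2 fold change of this comparison by 0.538 and gave 13325 higher and 6953 lower; against Stevens the shift was 0.505, with 14546 higher and 9006 lower.

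Within genotypes, the 0 min libraries of the cold series and of the heat series differed in few features. In Stevens, edgeR called 2 (0 to 3 with 1 library left out, 26 when only its own libraries were fitted and 11 with the replicate number as a block), Vaccinium_macrocarpon.helixer.a04.chr07.g175480, higher in the cold series at 95.1 against 10.4 CPM, and Vaccinium_oxycoccos.helixer.a04.chr03.g067240, lower at 0 against 1.43 CPM (edgeR adjusted p = 0.0218 for each). In Stevens × NJ96-95 it called 2 as well (0 to 4 with 1 library left out, 0 with RLE scaling, 0 without the low-count filter, 11 with DESeq2, 9 when only its own libraries were fitted and 9 with the block), both higher in the cold series: Vaccinium_oxycoccos.helixer.a04.chr02.g045340 and Vaccinium_oxycoccos.helixer.a04.chr09.g196380 (edgeR adjusted p = 0.0302 for each). These 4 features fall outside the fixed rule and were named after their values were seen. In the Ben Lear, NJ96-20 × Stevens and Pilgrim hybrids edgeR called 0 features and DESeq2 called 2, 3 and 11. Of 28437 features tested, 1310, 1156 and 667 had an unadjusted p under 0.05, each below the share of 0.05 that no difference would give. When only their own libraries were fitted, edgeR called 1, 3 and 0, and with the block it called 1, 0 and 4.

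Heat at 30 min, when 47 °C was recorded, changed many features in the same direction in every genotype. In Stevens 793 rose and 515 fell, and over the mean of the 4 hybrids 2949 rose and 4138 fell (edgeR, adjusted p under 0.05, 26592 features tested). Of the Stevens calls, 303 rises and 367 falls were macrocarpon features. The other 490 and 148 were oxycoccos features, which in Stevens carry mostly reads assigned across species. Of the hybrid calls, 841 rose and 2854 fell by over 2-fold. Separately called lists shared many members: 110 of the 13852 macrocarpon features tested rose in all 5 genotypes and 35 fell in all 5, where independent lists of these sizes would share 0.000281 and 0.000386. On the oxycoccos side, 95 features rose and 24 fell in all 4 hybrids. Of the 303 macrocarpon features called up in Stevens, 301 had the same sign in the hybrid mean and 277 were called there, with median log2 fold changes of 2.40 in Stevens and 1.91 in the hybrids. A list favours the side it was called in: over the 1642 called up in the hybrid mean, the medians were 0.52 in Stevens and 0.71 in the hybrids. Of the 367 called down, 362 had the same sign and 313 were called. Leaving out 0 min replicate 2 or 3 lowered the Stevens count of 1308 to 836 or 869, and thinning to equal depth to 824, while a fit to the Stevens libraries alone gave 624 up and 636 down. Over the mean of the hybrids the count stayed between 6529 and 7234 with any 1 library left out.

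The strongest rises at 30 min of heat started from almost no reads. In Stevens, Vaccinium_macrocarpon.helixer.a04.chr09.g223510 went from 0.561 ± 0.319 CPM at 0 min to 575 ± 190 at 15 min and 821 ± 143 at 30 min (SD, n = 3; log2 fold change at 30 min 10.35 ± 0.72 SE, edgeR adjusted p = 1.31e-13), and it rose in the hybrid mean by 10.29 ± 0.40 on the log2 scale (edgeR adjusted p = 2.65e-22). Vaccinium_oxycoccos.helixer.a04.chr01.g001880, an oxycoccos feature that also takes reads in Stevens, went from 0.501 to 757 ± 208 CPM there. In the hybrids, Vaccinium_oxycoccos.helixer.a04.chr07.g165300 had 0 reads in the 12 libraries at 0 min and 196 CPM at 30 min, at least 1590-fold higher, and Vaccinium_oxycoccos.helixer.a04.chr09.g211160 rose from 0.37 to 595 CPM, a ratio of 1610 (95% interval 849 to 3520). The largest falls were smaller and rested on few reads: in Stevens, Vaccinium_macrocarpon.helixer.a04.chr12.g289030 fell from 16.2 ± 4.0 to 0.33 ± 0.33 CPM (edgeR adjusted p = 0.000197), a ratio of 58.6 (19.8 to 287), and Vaccinium_macrocarpon.helixer.a04.chr02.g049460 from 5.46 ± 2.82 CPM to a single read, a ratio of 58.0 (10.0 to 2330), with an edgeR adjusted p of 0.00261 that became 0.0532 at equal depth. Vaccinium_oxycoccos.helixer.a04.chr10.g221580 and Vaccinium_oxycoccos.helixer.a04.chr12.g282350 fell 21.5-fold (11.8 to 43.6) and 17.6-fold (9.85 to 34.5) over the hybrids.

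Single hybrids had 702 features up and 552 down at 30 min (Ben Lear), 722 and 769 (NJ96-20 × Stevens), 1072 and 1607 (Pilgrim) and 561 and 503 (Stevens × NJ96-95). These counts depended on single libraries. For the Ben Lear hybrid, 1254 became 643 without 0 min replicate 3 and 791 or 808 without 30 min replicate 1 or 3. For NJ96-20 × Stevens, 1491 became 771 or 725 without 0 min replicate 1 or 3, and 898, 824 or 874 without 30 min replicate 1, 2 or 3. For Pilgrim, 2679 became 1405 or 1383 without 0 min replicate 1 or 3, and 1596 or 1567 without 30 min replicate 1 or 2. For Stevens × NJ96-95, 1064 became 760 without 30 min replicate 3, whose library name carries another time code than its title. Fitting only the libraries of the genotype gave 3763 for NJ96-20 × Stevens, 1475 for Pilgrim and 589 for Stevens × NJ96-95, so the hybrids are not ranked by count. Nor did the balance of rises and falls hold in 3 of them: it was 789 up and 825 down with DESeq2 and 614 and 749 in its own fit for Ben Lear, 1913 and 1850 in its own fit for NJ96-20 × Stevens, and 540 and 562 with RLE scaling and 657 and 764 with DESeq2 for Stevens × NJ96-95.

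**Figure D2:**
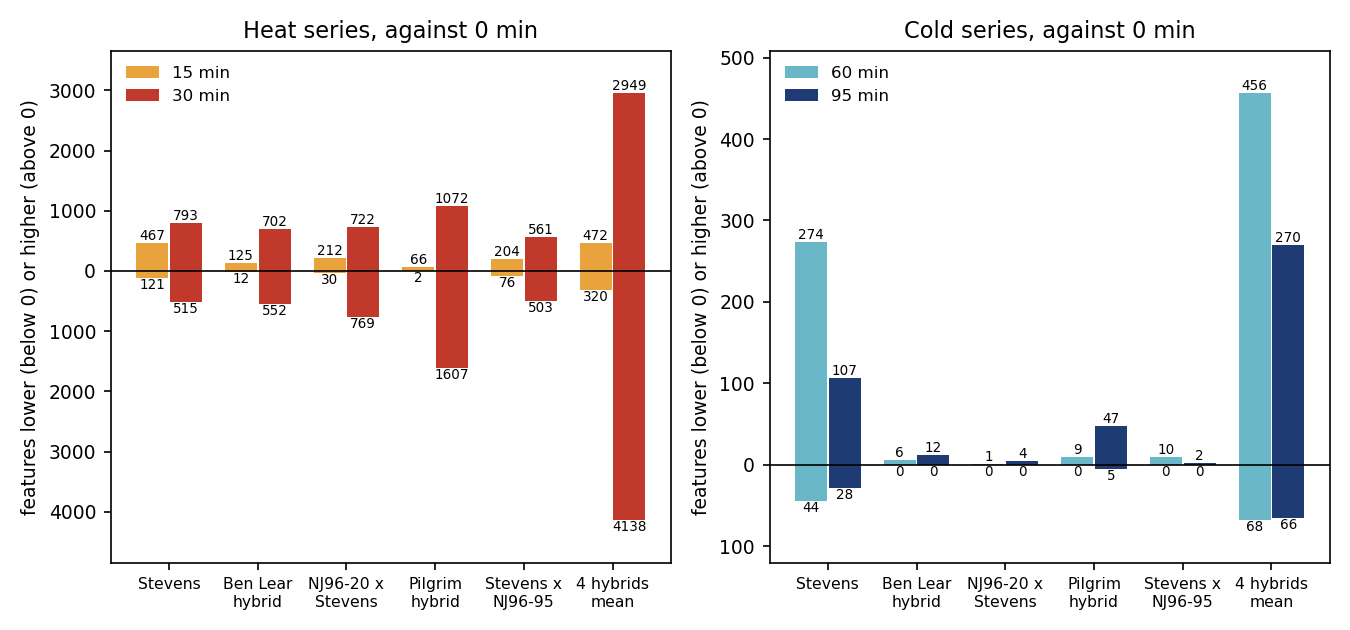
Number of features called higher (bars above 0) or lower (bars below 0) than at 0 min (vertical axis) in each genotype and in the mean of the 4 hybrids (horizontal axis), in heat at 15 and 30 min and in cold at 60 and 95 min; numbers beside bars are counts, and the axes of the panels differ in scale. The hybrid mean rests on 24 libraries and each genotype on 6, so its 2949 rises and 4138 falls at 30 min of heat are not comparable in number with those of single genotypes. Counts for Stevens include oxycoccos features, among them 490 of its 793 rises at 30 min of heat.

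At 15 min, when 39.7 °C was recorded, rising features had moved further in Stevens than in the hybrids. In Stevens 467 features rose (243 macrocarpon, 224 oxycoccos) and 121 fell (94 and 27), with a median log2 fold change of 3.05 over macrocarpon features called up. The same 243 features had a median of 0.98 in the hybrid mean, where 230 had the same sign and 133 were called. Over the 269 called up in the hybrid mean the medians were 1.24 in Stevens and 0.88 in the hybrids. For falls the order depended on the list: medians were −2.18 in Stevens and −0.85 in the hybrids over the 94 called down in Stevens, but −1.19 and −1.17 over the 172 called down in the hybrid mean. Single hybrids had 125 up and 12 down (Ben Lear), 212 and 30 (NJ96-20 × Stevens), 66 and 2 (Pilgrim) and 204 and 76 (Stevens × NJ96-95), and the hybrid mean 472 and 320. Still, 35 macrocarpon features rose in all 5 genotypes at 15 min, and 29 oxycoccos features in all 4 hybrids. The NJ96-20 × Stevens count of 242 was 160 without 15 min replicate 2, 440 with DESeq2 and 1132 when only its own libraries were fitted. Without the low-count filter the 4 hybrids, in the order above, had 267, 487, 146 and 500 calls in all.

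Tested directly as an interaction, the response at 15 min differed between the hybrid mean and Stevens in 206 features, 27 with a higher and 179 with a lower log2 fold change in the hybrids (134 features without Stevens 0 min replicate 3, and 368 without the low-count filter). Oxycoccos features in Stevens carry mostly reads assigned across species, so the macrocarpon features are the clearer part: 95 had a lower and 17 a higher log2 fold change in the hybrids (193 in all without the low-count filter). Of the 95, 92 were called up in Stevens, with median log2 fold changes of 4.12 in Stevens and 1.23 in the hybrids at 15 min. These lists were chosen by the difference at 15 min, so their medians at that time restate the choice. At 30 min the medians of the 95 were 3.27 and 2.61, and the choice alone would narrow the gap in part. All 17 of the other list were called down in Stevens, and their medians at 15 min were −2.82 there and −0.78 in the hybrids. At 30 min the interaction gave 10 features with a higher and 72 with a lower log2 fold change, of which 1 and 1 were macrocarpon features, Vaccinium_macrocarpon.helixer.a04.chr04.g104450 (1.77 ± 0.35 SE on the log2 scale, edgeR adjusted p = 0.00367) and Vaccinium_macrocarpon.helixer.a04.Unknown.g000390 (−1.85 ± 0.44, edgeR adjusted p = 0.0463), named after their values were seen (689 macrocarpon features had an unadjusted p under 0.05). Of 13852 macrocarpon features tested, 689 is close to the share of 0.05 that unadjusted p-values give where nothing differs. DESeq2 called 185 features at 30 min, 22 of them macrocarpon, edgeR without the low-count filter 235, 68 of them macrocarpon, and libraries thinned to equal depth gave 37. RLE scaling gave 5 macrocarpon features at 30 min, and the fit of macrocarpon features alone gave 0. A mean can hide hybrids that go both ways: set against Stevens one by one at 30 min, in tests not refitted with other settings, edgeR called 25 macrocarpon features higher and 11 lower in Ben Lear, 2 and 16 in Pilgrim, 7 and 7 in Stevens × NJ96-95, and 0 in NJ96-20 × Stevens (815 with an unadjusted p under 0.05). For the hybrid mean, the macrocarpon count at 30 min lay between 1 and 10 with 1 library left out, the highest without 0 min replicate 1 of Stevens × NJ96-95.

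The features leading the 30 min interaction had few or no reads in Stevens at 0 min. Vaccinium_oxycoccos.helixer.a04.chr04.g093850 rose in every hybrid, from 25.3 ± 10.9 to 685 ± 94 CPM in the Ben Lear hybrid (SD, n = 3), against 0.722 and 0.222 CPM in Stevens (interaction 6.01 ± 0.97 SE on the log2 scale, edgeR adjusted p = 0.000301, and 0.0845 at equal depth). Vaccinium_oxycoccos.helixer.a04.chr05.g120900 went from 0 reads to 9.74 ± 1.42 CPM in Stevens and from 5.31 to 11.3 CPM in the Pilgrim hybrid (interaction −6.40 ± 1.06, edgeR adjusted p = 0.000453). Vaccinium_oxycoccos.helixer.a04.chr09.g209720 (4.22 ± 0.76, edgeR adjusted p = 0.00241) and Vaccinium_oxycoccos.helixer.a04.chr07.g163360 (−7.06 ± 1.36, edgeR adjusted p = 0.00741, and 0.118 at equal depth) complete the list, and all but Vaccinium_oxycoccos.helixer.a04.chr05.g120900 lost the call in 1 of the fits with a library left out.

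A heat set chosen without the genotype being scored, a measure added after the data had been seen, gave the same contrast between Stevens and the hybrids. Its macrocarpon features, called up at 30 min in at least 3 of the other 4 genotypes, rose at 15 min by 3.50 ± 0.18 in Stevens (mean log2 change, SD, n = 3; 167 features) and by 1.75 ± 0.20 in the Ben Lear hybrid, 1.95 ± 0.28 in NJ96-20 × Stevens, 0.93 ± 0.31 in the Pilgrim hybrid and 2.00 ± 0.23 in Stevens × NJ96-95. Each genotype was thus scored on its own list, of 176 to 189 features in the hybrids, so the tests compare means over different lists. Stevens exceeded the hybrid mean by 1.85 (exact permutation test of 3 against 12 libraries, p = 0.0022, adjusted over 4 tests 0.0088), with all 12 hybrid libraries below. At 30 min the set stood at 3.66 in Stevens and 3.42 in the hybrids, a difference of 0.24 that did not pass the test (exact permutation p = 0.389, adjusted 0.424), and the hybrids ranged from 2.86 (Pilgrim) to 4.03 (Ben Lear). The set that fell had changed by −0.93 in Stevens and −0.56 in the hybrids at 15 min (exact permutation p = 0.00879, adjusted 0.0176), and by −1.74 and −1.61 at 30 min (p = 0.424 by the same test). With genotypes as the unit, 1 against 4 cannot give a p below 0.2. Oxycoccos features called up in other hybrids, chosen by their own calls and not matched to macrocarpon features, rose by 0.84 to 1.99 at 15 min and by 2.37 to 3.15 at 30 min.

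**Figure D3:**
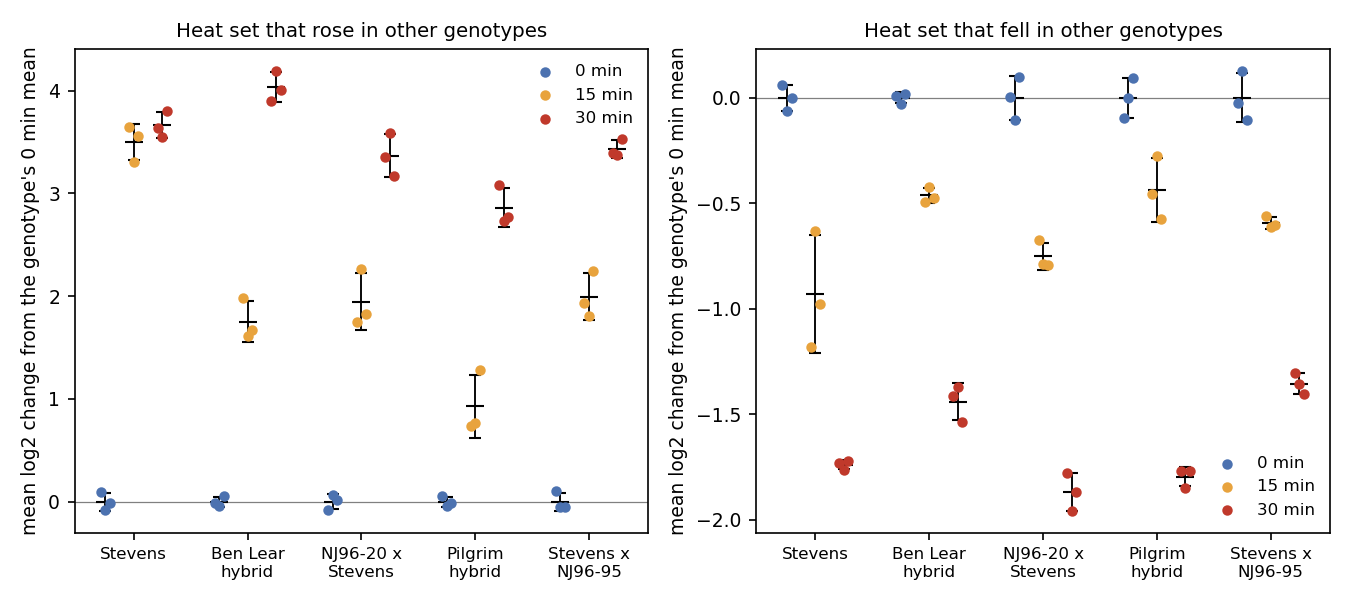
Mean log2 change from the 0 min mean of the same genotype (vertical axis) for macrocarpon features that rose or fell at 30 min in at least 3 of the other 4 genotypes, by genotype (horizontal axis) at 0, 15 and 30 min of heat; points are libraries, and bars are means with SD (n = 3). At 15 min the rising set stands at 3.50 in Stevens and at 0.93 to 2.00 in the hybrids, and at 30 min at 3.66 and at 2.86 to 4.03.

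Some of the largest rises fell on neighbouring features of chromosome 7, in both species' models, a group singled out after its values were seen. Numbers in the feature names are taken to follow position. The group comprises 6 of the 7 tested macrocarpon features from Vaccinium_macrocarpon.helixer.a04.chr07.g177160 to Vaccinium_macrocarpon.helixer.a04.chr07.g177220 and the 5 tested oxycoccos features from Vaccinium_oxycoccos.helixer.a04.chr07.g165900 to Vaccinium_oxycoccos.helixer.a04.chr07.g165950. All 6 macrocarpon members rose in all 5 genotypes at both times, by 8.12 to 13.0 on the log2 scale at 30 min, and all 5 oxycoccos members rose in every hybrid at 30 min. How reads were divided among such neighbours is not given in the sources used here, so only sums of their reads are compared between genotypes. Together the 11 features took 0.0101% of reads in Stevens at 0 min, 4.07% ± 0.59 at 15 min and 5.58% ± 0.65 at 30 min (SD, n = 3). In the hybrids they took 0.00637%, 0.731% ± 0.30 and 3.06% ± 0.81 (n = 12). Stevens was 5.56-fold above the hybrids at 15 min and 1.83-fold at 30 min (exact permutation p = 0.0022 for each, adjusted 0.0033), and 1.58-fold at 0 min (exact permutation p = 0.0176). These p-values take libraries as units, for a group chosen after its values were seen. By genotype, 1 against 4 cannot give a p below 0.2, and sequencing run may coincide with genotype.

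**Figure D4:**
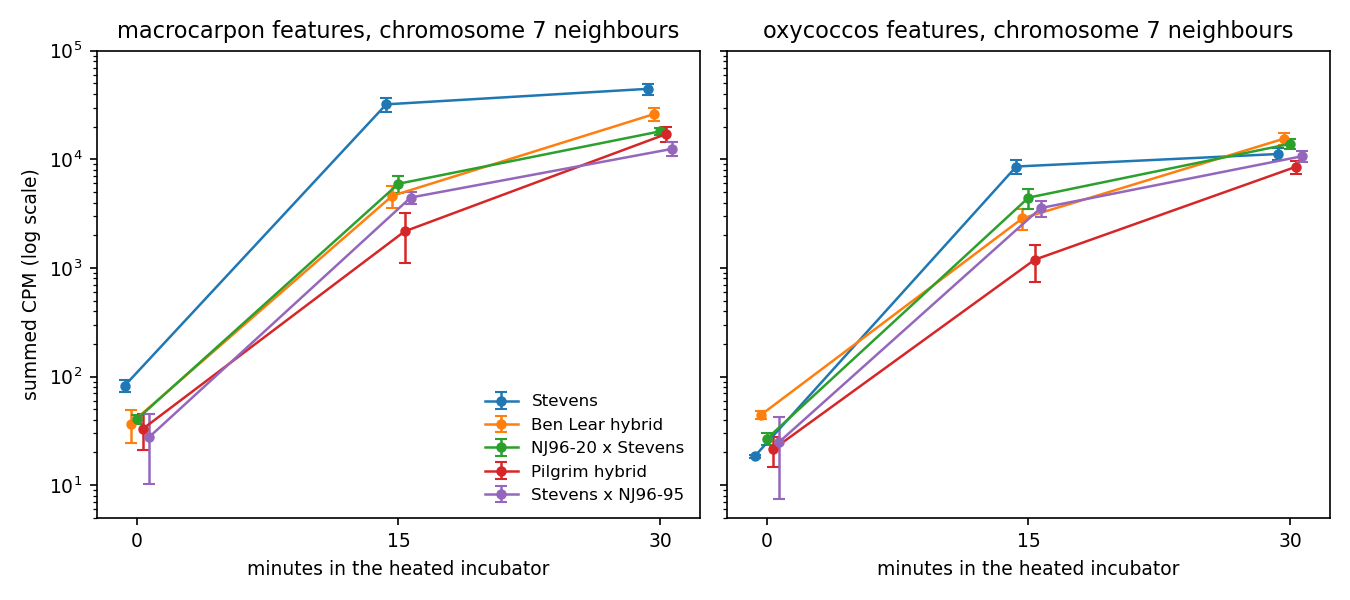
Summed CPM (vertical axis, log scale) of the 6 macrocarpon features (left) and 5 oxycoccos features (right) of the chromosome 7 group against minutes of heat (horizontal axis), with lines for genotypes and bars for SD (n = 3). In Stevens the macrocarpon sum goes from 82.2 to 32100 CPM at 15 min and the oxycoccos sum from 18.4 to 8590 CPM. At 15 min the hybrids stand at 2170 to 5960 CPM on the macrocarpon and 1190 to 4440 CPM on the oxycoccos features.

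Heat also lowered the number of features seen in the hybrids. Rarefied to 461274 reads, hybrid libraries held 26630 features at 0 min, 25280 at 15 min and 23140 at 30 min (means of 4 genotypes, n = 12). The number fell by 1350 and by 3490 features (permutation test stratified by genotype, p = 0.00161 and 1e-05, the latter the smallest that the resamples can give, adjusted 0.0193 and 0.00024), and the 30 min mean was below 0 min in each of the 4 hybrids. In Stevens, 19300 features were seen at 0 min and 18180 at 30 min, a difference that 3 against 3 libraries cannot call (exact permutation p = 0.1, the smallest possible). Cold moved the number by 459 at 60 min and by 411 at 95 min in the hybrids, short of the test (stratified permutation p = 0.191 and 0.197, adjusted 0.343).

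**Figure D5:**
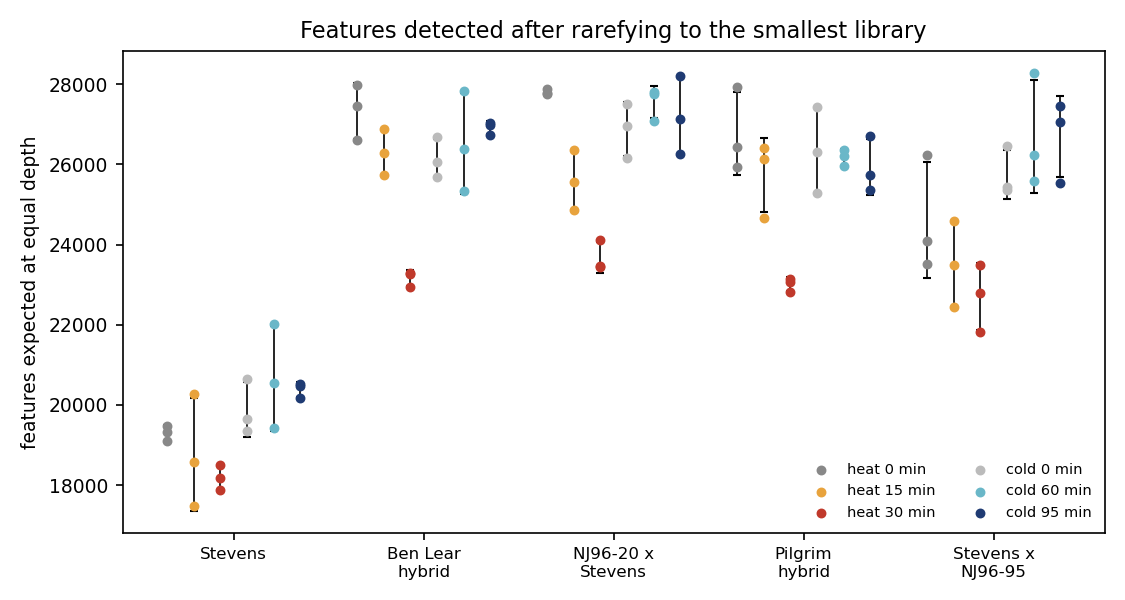
Number of features with at least 1 read expected after rarefying each library to 461274 reads (vertical axis) by genotype (horizontal axis), with a column of 3 libraries per time, points for libraries and bars for mean and SD. The 30 min heat libraries average 23140 features over the hybrids, against 26630 at 0 min.

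Cold gave far fewer calls than heat, and 1 macrocarpon feature was called in all 5 genotypes at both times. It is Vaccinium_macrocarpon.helixer.a04.chr02.g047900, which the fixed rule also names: it rose from 28.6 ± 3.8 to 172 ± 25 CPM in Stevens at 95 min (SD, n = 3; 2.58 ± 0.30 SE on the log2 scale, edgeR adjusted p = 1.53e-07), and by 1.95 to 2.54 in the 4 hybrids (hybrid mean 2.34 ± 0.17, edgeR adjusted p = 4.1e-15). At 60 min its rise was 2.13 ± 0.30 in Stevens and 2.29 ± 0.17 in the hybrid mean, while heat did not move it past the test (edgeR adjusted p = 0.393 in Stevens and 0.749 in the hybrid mean at 30 min). At 60 min, at 10.5 °C, 274 features rose (108 macrocarpon, 166 oxycoccos) and 44 fell (31 and 13) in Stevens, and 456 rose and 68 fell over the mean of the hybrids (edgeR, 29056 features tested). At 95 min, at 3 °C, 107 rose (60 macrocarpon, 47 oxycoccos) and 28 fell (16 and 12) in Stevens, and 270 rose and 66 fell in the hybrid mean. The Stevens counts rest on single libraries: 318 at 60 min became 143, 78 or 60 without 0 min replicate 1, 2 or 3, 37 without 60 min replicate 2, 506 without 60 min replicate 3 and 59 at equal depth, and 135 at 95 min became 67, 27 or 27 without 0 min replicate 1, 2 or 3, 59, 72 or 74 without 95 min replicate 1, 2 or 3 and 20 at equal depth. The hybrid mean at 60 min, 524 calls, became 349 without 60 min replicate 2 of the Ben Lear hybrid and 342 at equal depth, and DESeq2 called 546 where edgeR called 336 at 95 min. Other settings raised the counts. Without the low-count filter Stevens had 677 calls at 60 min and 421 at 95 min, and the hybrid mean 1031 and 775. DESeq2 called 481 and 239 in Stevens.

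Features that rose in the cold in Stevens tended to rise in the hybrids. Of 108 macrocarpon features called up in Stevens at 60 min, 100 had the same sign in the hybrid mean and 49 were called there, where independent lists would share 1.87; medians were 1.5 in Stevens and 0.59 in the hybrids. Over the 262 called up in the hybrid mean the order turned, with medians of 0.82 in Stevens and 1.11 in the hybrids. At 95 min these numbers were 60 of 60 with the same sign and 33 called, against 0.629, with medians of 1.63 and 0.86, and of 0.93 and 0.95 over the 159 called up in the hybrid mean. In the hybrid mean at 95 min, Vaccinium_oxycoccos.helixer.a04.chr02.g046670 rose 5.13-fold (95% interval 4.21 to 6.30; log2 fold change 2.37 ± 0.29 SE, edgeR adjusted p = 7.8e-07), with 0 reads in Stevens. Vaccinium_macrocarpon.helixer.a04.chr05.g125980 fell 2.32-fold (1.75 to 3.09; edgeR adjusted p = 0.00128) and Vaccinium_oxycoccos.helixer.a04.chr11.g248600 1.72-fold (1.57 to 1.90; edgeR adjusted p = 0.000192), the only falls that met the fixed rule. In Stevens, Vaccinium_macrocarpon.helixer.a04.chr01.g026510 rose from 10.4 ± 1.1 to 127 ± 38 CPM (edgeR adjusted p = 0.0489, and 0.0501 with RLE scaling), and Vaccinium_macrocarpon.helixer.a04.chr11.g276490 from 0.727 to 45.6 ± 65.9 CPM, with 121.6 CPM in 1 library (edgeR adjusted p = 0.0432, and 0.0726 with DESeq2). Vaccinium_oxycoccos.helixer.a04.chr09.g204560 fell from 12.6 ± 4.9 to 1.42 ± 0.55 CPM (edgeR adjusted p = 0.00268) and Vaccinium_macrocarpon.helixer.a04.chr01.g026920 from 11.3 ± 3.7 to 1.56 ± 0.41 CPM (edgeR adjusted p = 0.0154). Of these, Vaccinium_oxycoccos.helixer.a04.chr09.g204560 alone kept its call without any 1 library.

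Single hybrids, the Ben Lear and NJ96-20 × Stevens ones at low depth, had few calls in the cold in the fit to all genotypes. That depended on the fit: without the low-count filter the 4 hybrids had 169 to 388 calls at 60 min and 136 to 753 at 95 min. DESeq2 gave 22 to 74 and 15 to 201. When only its own libraries were fitted, Ben Lear had 158 and 114. In such fits NJ96-20 × Stevens had 5 and 8, Pilgrim 1 and 2, and Stevens × NJ96-95 36 and 5. At 95 min the 2 calls of Stevens × NJ96-95 were neighbours in name, Vaccinium_macrocarpon.helixer.a04.chr02.g047900 and Vaccinium_macrocarpon.helixer.a04.chr02.g047890, the latter at 7.84 CPM at 0 min and 34.9 at 95 min (2.15 ± 0.34 SE on the log2 scale, edgeR adjusted p = 0.000941). NJ96-20 × Stevens had the same features among its 4, with Vaccinium_macrocarpon.helixer.a04.chr09.g215680 (24.2 to 145 CPM) and Vaccinium_macrocarpon.helixer.a04.chr11.g255970 (0 to 9.62 CPM), and its 1 call at 60 min was Vaccinium_macrocarpon.helixer.a04.chr02.g047900. Features outside the fixed rule were named here after their values were seen. The Ben Lear, Pilgrim and Stevens × NJ96-95 hybrids had 6, 9 and 10 features up at 60 min (0 to 5, 4 to 33 and 2 to 38 with 1 library left out), and Ben Lear and Pilgrim 12 and 47 at 95 min, where Pilgrim also had 5 down. The Ben Lear count of 12 was 1 without 0 min replicate 3. The Pilgrim total of 52 became 168 without 0 min replicate 2, 11 or 2 without 0 min replicate 1 or 3, and 7 or 13 without 95 min replicate 2 or 3. In the edgeR fit to all genotypes with the low-count filter, 0 features fell in any hybrid at 60 min. Without the filter edgeR called 85, 56, 141 and 85 down and DESeq2 7, 1, 0 and 2 (Ben Lear, NJ96-20 × Stevens, Pilgrim and Stevens × NJ96-95), and edgeR called 42 down for Ben Lear when only its own libraries were fitted and 1 at equal depth. Of 29056 features tested, 1430 to 2078 per hybrid had an unadjusted p under 0.05 in either direction. The lowest of these counts is about the share of 0.05 that no difference would give, and the highest exceeds it.

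No difference between the hybrids and Stevens in the cold response stood on firm ground. The interaction called 15 features at 60 min and 5 at 95 min, all with a lower log2 fold change in the hybrids, of which 1 and 0 were macrocarpon features (Vaccinium_macrocarpon.helixer.a04.chr07.g169610 at 60 min, −3.12 ± 0.55 SE on the log2 scale, edgeR adjusted p = 0.0112, named after its value was seen; 842 and 630 macrocarpon features had an unadjusted p under 0.05; DESeq2 called 25 and 0). Of 15163 macrocarpon features tested, 842 lies somewhat above and 630 below the share of 0.05 that no difference would give. Direction at 60 min was not stable either: DESeq2 called 20 features higher and 46 lower in the hybrids, with 17 of its 25 macrocarpon features higher, and the fit without the low-count filter 96 and 234. At 95 min the fit without the filter called 28 higher and 118 lower, with 86 macrocarpon features among them (17 higher, 69 lower). At equal depth the interaction counts at 60 and 95 min were both 0. The 60 min count was 144, 1 or 104 without Stevens 60 min replicate 1, 2 or 3, 6 or 4 without Stevens 0 min replicate 2 or 3, 23 without 60 min replicate 2 of Stevens × NJ96-95 and 24 without 60 min replicate 2 of the Pilgrim hybrid. At 95 min the count was 0, 3 or 10 without Stevens 95 min replicate 1, 2 or 3 and 1 without Stevens 0 min replicate 2 or 3. Of the 5 features at 95 min, the fixed rule named 2, oxycoccos features with almost no reads in Stevens. Vaccinium_oxycoccos.helixer.a04.chr01.g019530 went from 0.149 to 2.76 ± 1.46 CPM in Stevens and from 13.2 to 16.0 CPM in the Pilgrim hybrid (edgeR adjusted p = 0.0143, and 0.179 with DESeq2), and Vaccinium_oxycoccos.helixer.a04.chr02.g029590 from 0 reads to 0.956 ± 0.241 CPM in Stevens and from 7.55 to 6.94 CPM in the Pilgrim hybrid (edgeR adjusted p = 0.0441, and 0.179 with DESeq2). With 1 library left out, the former lost its call in 3 of 30 fits and the latter in 24 of 30. The others were Vaccinium_oxycoccos.helixer.a04.chr01.g006500, Vaccinium_oxycoccos.helixer.a04.chr06.g124090 and Vaccinium_oxycoccos.helixer.a04.chr11.g245510 (edgeR adjusted p = 0.0143, 0.00968 and 0.0101), named after their values were seen.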

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

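In this part the heat set and its tests, the thinning to the hybrids' macrocarpon totals, every test on V. oxycoccos plant 4 and the comparison of detected features at equal depth were chosen only after the result was seen.

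Stevens had changed more at the earlier time of heat: at 15 min, 95 macrocarpon features had a lower and 17 a higher log2 change in the hybrid mean than in Stevens, and the heat set stood 1.85 higher in Stevens for rising features and −0.369 apart for falling ones, by tests of the difference itself. Fewer reads on macrocarpon features in the hybrids do not account for the rising set, since Stevens thinned to the hybrids' mean macrocarpon total kept a score of 3.45 ± 0.17 (SD, n = 3) against at most 2.00 in a hybrid. Other library totals or scaling in Stevens would also act at 30 min, where the difference was 0.24. A sequencing run or handling day that goes with the genotype stays open and cannot be told apart from genotype, because the 9 heat libraries of Stevens could all lie in 1 run of 9 libraries, and a slightly faster rise of leaf temperature in that batch could give the same values. A difference between cultivated cranberry and hybrids in the speed of the heat response is a biological explanation that the design names and that was not tested, with a single macrocarpon genotype on 1 side.

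V. oxycoccos plant 4 lay apart in its share of reads on oxycoccos features, 66.8% against 81.3% to 83.8% in the other 3 plants (ratio of gap to range 0.854, limit 0.829; chance alone marks about 1 in 20 such groups, and 5 measures were looked at). Stevens RNA mixed into the library would need a fraction of 20.9% and would raise nearly every macrocarpon feature, but of 1360 macrocarpon features abundant in Stevens and under 2% of its level in the other 3 plants, 33.4% stayed under 2% in plant 4 (0.368% in the hybrids). A library of one of the 4 hybrids under the oxycoccos label is argued against by the share itself, 66.8%, as the highest hybrid library had 51.1%. What stays open is that alleles of this plant may lie closer to the macrocarpon models in stretches of the genome: 799 neighbouring pairs of these features fell in 1 class, against 790 in the highest of the permuted orders, yet neighbours can also be alike through shared expression. Its genotype differs from those of the other plants, and no biological explanation beyond that was tested.

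Fewer features were detected after 30 min of heat in the hybrids, a fall that a few induced features taking most of the reads could give. Without the 243 features above 0.1% of the reads of any hybrid heat library, the number detected at equal depth still changed by −2812, against −3427 with all features at the matching depth, so these features are argued against as the whole cause. The change of −3490 was itself taken at equal depth, which removes differences in library totals by design, so it holds no test of lower library totals after heat. RNA integrity was not analysed here and stays open, as does a real loss of low-abundance transcripts.

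At 30 min of heat 1 macrocarpon feature had a higher and 1 a lower log2 change in the hybrid mean than in Stevens, and at 60 min of cold 1 had a lower change, by tests of the difference itself.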

How the results depend on the processing

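In this part, the fits at equal depth and on macrocarpon features alone were chosen only after the data had been seen. No named feature and no difference in shares changed sign, but the balance of higher and lower calls turned in several comparisons. Counts within 1.5 times of the reported ones numbered 38 of 40 with RLE scaling, 15 of 40 without the low-count filter, 19 of 40 with DESeq2, 12 of 29 in fits to 1 genotype, 32 of 37 with the replicate block and 21 of 32 at equal depth, and the cause of the changes was not tested. Named features kept their call in 29 of 30 cases with RLE scaling, 30 of 30 without the filter, 25 of 29 with DESeq2, 15 of 16 in fits to 1 genotype, 21 of 22 with the replicate block, 12 of 17 at equal depth and 535 of 580 with 1 library left out. The share of reads on oxycoccos features kept its difference (68.3 to 74.0 points). The cold series of the Ben Lear and NJ96-20 × Stevens hybrids had the lowest totals, and at equal depth the deeper Stevens cold series fell to 59 and 20 calls. Hybrids are given below in the order Ben Lear, NJ96-20 × Stevens, Pilgrim, Stevens × NJ96-95.

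The balance turned, given as up and down, at 30 min of heat for Stevens in its own fit (624 and 636), for Ben Lear with DESeq2 (789 and 825) and in its own fit (614 and 749), for Stevens × NJ96-95 with RLE scaling (540 and 562) and DESeq2 (657 and 764), and for NJ96-20 × Stevens in its own fit (1913 and 1850) and without any 1 of its 30 min libraries (480 and 418, 445 and 379, 455 and 419). It also turned at 95 min of cold without the low-count filter for NJ96-20 × Stevens (58 and 78) and Pilgrim (306 and 447), for macrocarpon features in the 60 min interaction with DESeq2 (17 and 8) and without certain libraries (2 and 1, 2 and 1, 4 and 1, 3 and 0), at baseline for macrocarpon features fitted alone (922 and 900), for the series controls of Stevens × NJ96-95 in its own fit (4 and 5), and for V. oxycoccos against the hybrids without plant 4 (9984 and 10243).

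Without the low-count filter, hybrids had 267, 487, 146 and 500 calls at 15 min of heat, 238, 169, 388 and 324 at 60 min of cold and 171, 136, 753 and 147 at 95 min. Stevens had 677 and 421 in the cold and the hybrid mean 1031 and 775. Interactions gave 368 (193 macrocarpon) and 235 (68) in heat and 330 (155) and 146 (86) in cold, and the series controls of Stevens × NJ96-95 gave 0. RLE scaling gave 5 macrocarpon features in the 30 min interaction and 0 for those controls.

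With DESeq2, NJ96-20 × Stevens had 440 calls at 15 min of heat. Stevens had 481 at 60 min of cold and 239 at 95 min, hybrids 28, 22, 35 and 74, then 51, 15, 201 and 19, and the hybrid mean 546 at 95 min. Interactions gave 185 (22 macrocarpon) at 30 min of heat, 66 (25) at 60 min of cold and 1 at 95 min, and series controls 2, 3, 11 and 11 in the hybrids.

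Fits to the libraries of 1 genotype gave 1132 calls at 15 min and 3763 at 30 min of heat in NJ96-20 × Stevens, and 1475 and 589 at 30 min in Pilgrim and Stevens × NJ96-95. At 60 min of cold they gave 203 in Stevens and 158, 5, 1 and 36 in the hybrids, at 95 min 114, 8, 2 and 5, and for series controls 26 in Stevens and 1, 3 and 9 in Ben Lear, NJ96-20 × Stevens and Stevens × NJ96-95.

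At equal depth, Stevens had 824 calls at 30 min of heat, 59 at 60 min and 20 at 95 min of cold. NJ96-20 × Stevens had 3 at 60 min, Pilgrim 12 and Stevens × NJ96-95 5 at 95 min, and the hybrid mean 342 at 60 min. Interactions gave 37 at 30 min of heat, 0 at 60 min (0 macrocarpon) and 0 at 95 min of cold. Macrocarpon features fitted alone were set against the macrocarpon calls of the fit to both species: 1822 at baseline, and 0 in the interactions at 30 min of heat and 60 min of cold.

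With the replicate number as a block, the 60 min interaction gave 2 macrocarpon features and the series controls 11 in Stevens, 1 in Ben Lear, 4 in Pilgrim and 9 in Stevens × NJ96-95. Same-numbered libraries did not deviate together: mean r was −0.0537 in heat (5 of 45 pairs above 0.1) and 0.0259 in cold (9 of 45), and 9 and 16 of 45 libraries correlated best with their own number, so the numbers were not taken to pair samples.

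With 1 library left out, counts ranged as follows. At 30 min of heat: 836 to 1096 (Stevens), 643 to 1444, 725 to 1273 and 1383 to 2825 (the first 3 hybrids). At 15 min: 160 to 264 (NJ96-20 × Stevens). Interactions: 134 to 270 at 15 min, 1 to 10 macrocarpon features at 30 min, 1 to 144 (0 to 27 macrocarpon) at 60 min and 0 to 10 at 95 min. At 60 min of cold: 37 to 506 (Stevens), 349 to 597 (hybrid mean), then 0 to 5, 0 to 2, 4 to 33 and 2 to 38. At 95 min: 27 to 74 (Stevens), then 1 to 17, 1 to 6, 2 to 168 and 1 to 3. Series controls: 0 to 3 (Stevens) and 0 to 4 (Stevens × NJ96-95). Where this left 2 libraries in a group, the spread was pooled over all groups.

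The planned tests of gene lists were not run, because no identifier is paired with a name. The planned comparison with TPM was not run separately, since the TPM values equal CPM.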

Other observations

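In this part the overlap of heat and cold lists, the map of neighbouring features and the test of their placement were chosen only after results were seen; the splits of the libraries were planned.

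Features that rose in the cold in the hybrids were called down in heat more often than in independent lists, and at 95 min also called up more often. Of 416 features called up at 60 min of cold and tested in both series, 131 were called down at 30 min of heat, where independent lists would share 65.5, and 55 were called up in both, against 45.1. At 95 min 70 of 260 were down in heat, against 41, and 51 up, against 28.2. In Stevens 41 of 272 features up at 60 min of cold were up in heat, against 7.6, and 8 down, against 5.35. Among Stevens features up at 95 min, 7 were up in heat, against 2.82, and 4 down, against 1.99. Of the 274 Stevens rises at 60 min, 166 were oxycoccos features, which in Stevens carry mostly reads assigned across species. All Stevens calls at 60 min, up and down, went from 318 to 37 without 60 min replicate 2. The series have separate 0 min libraries. Expected numbers assume independent lists and were not tested further.

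Features called up in the cold in the hybrid mean also lay next to one another by name more often than in permuted orders within chromosomes: 12 pairs among 261 macrocarpon features at 60 min (mean of 1000 permuted orders 4.53, highest 11) and 10 among 194 oxycoccos features (2.71, highest 9). Among all macrocarpon features called up at 30 min of heat, 192 pairs were not beyond permuted orders (mean 181, highest 218, permutation p = 0.183), while oxycoccos features called up gave 152 (133, highest 173, p = 0.039) and those called down 407 on the macrocarpon side (362, highest 411, p = 0.004) and 316 on the oxycoccos side (282, highest 326, p = 0.00999). In the hybrid mean, strongly induced features (log2 fold change above 7) formed 5 pairs on each side, and in Stevens 7 on the macrocarpon side. The highest permuted order had 2 each time. Oxycoccos features in Stevens formed 1. The chromosome 7 group was seen first, prompted this count and is part of it. Thresholds from 0 to 8 were also tried, and allowing for the choice of threshold the permutation p was 0.002 on the macrocarpon side of the hybrid mean. That p does not allow for the choice to count neighbours, made because this group had been seen, so chance placement is not excluded. Alike neighbours that share reads might inflate these counts, and read sharing was not tested.

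Other splits of the same libraries were each fitted to the compared libraries alone. Of 100 splits per comparison, only 1, the real one, gave as many calls for the hybrid mean at 15 min of heat (830, highest other 2), 30 min of heat (6428, 16), 60 min of cold (401, 2) and 95 min of cold (464, 1). These splits exchanged times within each hybrid, and they argue against a chance arrangement of the libraries. The real split alone also reached its count for hybrids against Stevens (17416, 2), for V. oxycoccos against Stevens (20151, 7234) and for V. oxycoccos against the hybrids (16271, 2222). Those splits mixed libraries of different genotypes and species, so fewer calls were bound to follow and they cannot exclude chance.

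For 3 against 3 libraries the 10 splits are too few for a share under 0.05. At 15 min of heat the real values were 529 in Stevens and 128, 1343, 32 and 221 in the hybrids (Ben Lear, NJ96-20 × Stevens, Pilgrim, Stevens × NJ96-95), with highest others of 1, 0, 0, 3 and 0. At 30 min they were 2218, 1171, 2939, 1275 and 614, each with 0. At 60 min of cold they were 118, 121, 17, 0 and 31, with 1, 0, 24, 0 and 0, and at 95 min 482, 237, 15, 0 and 28, with 2, 11, 5, 0 and 172. Series controls gave 26, 1, 3, 0 and 9, with 3, 0, 17, 1 and 5. As many calls as the real split came from 2 splits for NJ96-20 × Stevens at 60 min and for Stevens × NJ96-95 at 95 min, from 3 for the controls of NJ96-20 × Stevens, and from all 10 for Pilgrim at 60 min, at 95 min and in its controls. The split of Stevens × NJ96-95 with 172 calls, several times the real 28, points to a structure of these samples, which was not tested.

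For the interactions, each genotype in turn was set against the other 4, and these 5 splits are too few for a share under 0.05. With Stevens set apart, 95 macrocarpon features had a lower and 17 a higher change at 15 min of heat (highest other genotype 39 in all), and the counts were 2 at 30 min (113, with 4 of 5 splits giving as many), 1 at 60 min of cold (0) and 0 at 95 min (0, with 5 of 5).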
